A study of Homo sapiens with 4 samples.

How the data were processed

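Ribosomal RNA was removed from total RNA of MiaPaCa-2 and PANC-1 cells and linear RNA was digested with ribonuclease R, per the labels' protocols, so host gene messenger RNA was not measured and ratios of circular to linear RNA were not analysed here. Libraries were strand-specific with paired reads of 150 bases. The deposited table holds whole-number counts of back-splice reads per circRNA identifier for each of the 4 libraries, with no normalisation found in the values. The submitters' processing notes name cutadapt, FastQC, Bowtie2, TopHat2, TopHat and edgeR and the genome build GRCh38.p13. The circRNA caller and the total reads per library are not given in the sources used here. A total back-splice count is thus part of a library, and it depends on sequencing depth, on the digestion of linear RNA and on the amount of circRNA together. PCR copies could not be removed, so intervals cover counting error only.

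Columns were assigned to libraries by the column names that the labels give. The groups were MiaPaCa-2 control, MiaPaCa-2 TQ, PANC-1 control and PANC-1 TQ, with 1 library each. Identifiers with 0 in every library (51235 of 80821) were left out. Library scales came from TMM, computed with edgeR on the 827 identifiers that pass filterByExpr with the treatment groups, and were set to a geometric mean of 1. The design fixed before the data were examined asked for TMM but did not name the identifiers it is computed on. TMM over every identifier with a count was computed first, and its calls were seen before the filtered version was chosen. It had given MiaPaCa-2 TQ a factor of 1.58, against 1.10 with the filter, and the filtered factors are those of the edgeR fit. The choice matters for MiaPaCa-2, and the results of both versions are given. The scale of TQ relative to control was 0.417 in MiaPaCa-2 and 1.38 in PANC-1, where the totals had ratios of 0.351 and 1.40.

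Within a line, an identifier was called higher or lower in TQ where it had at least 10 counts over the 2 libraries, a normalised ratio of at least 2 or at most 0.5, and an exact 99% interval (conditional binomial, Clopper-Pearson) that excluded 1. No p-value was computed within a line. Where one library had 0 counts, the fold is a bound computed with a floor of 3 counts in that library. That bound leaves out the counting error of the other library, so the limit of the 99% interval, given beside it, is the more cautious one. On simulated counts with 200 changed identifiers, the rule recovered 13.0% of 2-fold, 51.0% of 4-fold and 84.5% of 8-fold changes in MiaPaCa-2 and 12.5%, 51.5% and 89.5% in PANC-1. With no changes it called 7 of 1130 and 9 of 2289 identifiers. The simulation held counting error only.

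Across lines, edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) was fitted with terms for cell line and treatment, which left 1 residual degree of freedom, and p-values were adjusted by Benjamini-Hochberg. Whether the libraries came from separate cultures is not given in the sources used here. Overlaps between lines were tested with Fisher's exact test. Correlations across identifiers used log2 ratios with a prior count of 1 per library and 100000 permutations. Identifiers detected were compared after random thinning to the smallest total, averaged over 100 thinnings. Alternatives were total counts, DESeq2 size factors, other minimums, folds and intervals, no ciRNA identifiers, DESeq2 in place of edgeR, no filter, fewer model terms and each library left out. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

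The rule for naming circRNAs, fixed before the data were examined, took the 10 higher and 10 lower identifiers per line whose 99% bound lay farthest from 1, up to 10 called in the same direction in both lines, up to 5 in opposite directions, the 5 with the lowest p in each direction of each edgeR fit, the 5 with most counts per library and a fixed set of known circRNAs. The table does not pair identifiers with host genes or coordinates, and no reference used here does so. At most 2 identifiers per direction are therefore printed for a comparison, and hsa_circ_0001278 leads those that went opposite ways. Host genes are given only for the 16 circRNAs fixed by circBase identifier, from the host named with that identifier beforehand, and 13 of these identifiers are listed in the table. Those of CDR1-AS, ZNF609 and DDX42 are not analysed here, nor are the circles of FBXW7 and CAMSAP1, which were fixed by coordinates. The 14 host gene lists and the sums per host gene were not run for the same reason.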

Results

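Circular RNAs (circRNAs), which are closed by a back-splice junction, were counted by sequencing in MiaPaCa-2 and PANC-1, established human pancreatic ductal adenocarcinoma cell lines, with and without thymoquinone (TQ), a compound of black seed. MiaPaCa-2 cells received 20 µM and PANC-1 cells 10 µM for 24 h, so that dose and cell line cannot be told apart. There was 1 library per line and treatment, 4 libraries in all, and the question was whether circRNA levels differed between treated and untreated cells. Ratios within a line therefore compare 2 libraries and have no replicate check, and their intervals cover counting error only. Of 80821 listed circRNA identifiers, 29586 had at least 1 count. Total back-splice counts were 45094 in MiaPaCa-2 control, 15819 in MiaPaCa-2 TQ, 48631 in PANC-1 control and 67964 in PANC-1 TQ. The identifiers with at least 1 count numbered 11105, 5089, 12081 and 14965 in the same order.

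Most counts belonged to circRNAs with a circBase number, the public catalogue of circRNAs, in every library. Their share of the counts was 70.1% in MiaPaCa-2 control (95% Clopper-Pearson interval 69.7 to 70.6), 68.2% in MiaPaCa-2 TQ (67.5 to 68.9), 69.0% in PANC-1 control (68.6 to 69.4) and 69.9% in PANC-1 TQ (69.5 to 70.2). Identifiers that start with ciRNA, the usual name for intronic circles, took 7.47% (7.23 to 7.72) of MiaPaCa-2 control and 9.24% (8.79 to 9.70) of MiaPaCa-2 TQ counts. In PANC-1 they took 4.87% (4.68 to 5.06) of control and 3.70% (3.56 to 3.84) of TQ counts, so that the ciRNA share was higher in the TQ library of one line and lower in that of the other. The identifier with most counts was hsa_circ_0001900 in MiaPaCa-2 control, with 410, and hsa_circ_0001380 in MiaPaCa-2 TQ, with 154. In both PANC-1 libraries it was hsa_circ_0001006, with 546 counts in control and 891 in TQ.

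After all libraries were thinned to 15819 counts, 6656 identifiers were detected on average in MiaPaCa-2 control, against 5089 in MiaPaCa-2 TQ. PANC-1 control had 6928 and PANC-1 TQ 7146 at that depth. At a minimum of 2 reads the MiaPaCa-2 order turned, with 2787 in thinned control and 2869 in TQ, and so did the PANC-1 order, with 2802 in control and 2666 in TQ.

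The circle of HIPK3 (hsa_circ_0000284), a serine/threonine kinase gene whose circle is abundant in many human cells, stood out among the circRNAs fixed before the data were examined. In MiaPaCa-2 it had 314 counts in control and 37 in TQ, a normalised ratio of 0.283 (99% interval 0.173 to 0.439) or 3.54-fold lower in the TQ library. This was the lowest ratio of the 41 identifiers with at least 100 counts over the 2 MiaPaCa-2 libraries, whose median ratio was 0.925. Their 5th percentile was 0.311, inside the interval of the HIPK3 circle, so its ratio did not stand apart from the next lowest ones. In PANC-1 the HIPK3 circle had 383 counts in control and 531 in TQ, a ratio of 1.003 (0.843 to 1.20). The MiaPaCa-2 ratio divided by the PANC-1 ratio was 0.282 (0.174 to 0.455, from counting error alone).

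The other fixed circRNAs with at least 10 counts in each line did not meet the rule of size, which asked for a ratio of at least 2 or at most 0.5 and a 99% interval that excluded 1. The circle of LDLRAD3 (hsa_circ_0006988) had a ratio of 0.770 (0.407 to 1.38) in MiaPaCa-2 and 1.81 (1.01 to 3.39) in PANC-1. That of ZKSCAN1 (hsa_circ_0001727), a zinc finger gene, had 0.520 (0.244 to 1.01) in MiaPaCa-2 and 1.08 (0.640 to 1.84) in PANC-1. The circle of FOXK2 (hsa_circ_0000816), a forkhead transcription factor gene, had 0.675 (0.213 to 1.77) and 1.57 (0.961 to 2.64). That of CORO1C (hsa_circ_0000437), an actin-binding protein gene, had 1.15 (0.726 to 1.77) and 1.07 (0.794 to 1.45), and that of MBOAT2 (hsa_circ_0007334) 1.20 (0.404 to 3.20) and 0.808 (0.460 to 1.43). The circle of CDYL (hsa_circ_0008285) had 1 and 4 counts in MiaPaCa-2 control and TQ and 2 and 10 in PANC-1, a PANC-1 ratio of 3.62 (0.539 to 80.0). Those of SMARCA5 (hsa_circ_0001445), UBAP2 (hsa_circ_0001846), RHOT1 (hsa_circ_0005397) and STIL (hsa_circ_0000069) had at most 4 counts in any library. The circles of PDE8A (hsa_circ_0036627) and ITCH (hsa_circ_0001141) had 0 in every library. Taken as 3 counts, this allows a share of up to 0.0190% of the counts in the shallowest one, from counting error alone. Zeros beyond counting error occurred in these libraries, so the bound does not limit the amount of the circle.

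**Figure D1:**
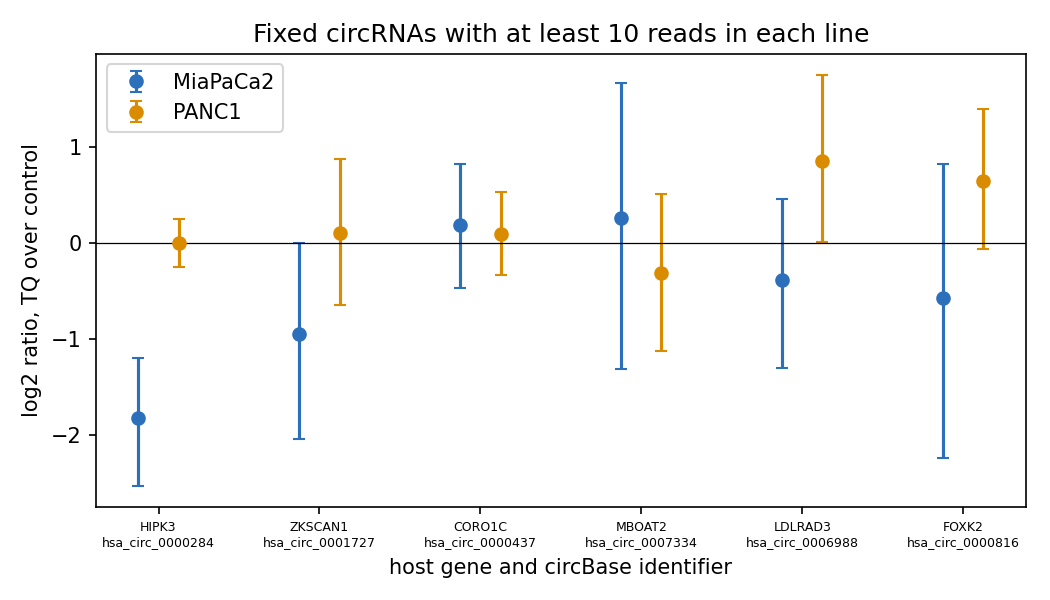
Log2 ratio of normalised counts, TQ over control, for the 6 fixed circRNAs with at least 10 counts in each line, by host gene and circBase identifier. Points are 1 pair of libraries per line and bars are exact 99% counting intervals; the HIPK3 circle lies at 0.283 of control in MiaPaCa-2 and at 1.003 in PANC-1.

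In MiaPaCa-2, 46 of 1130 identifiers with at least 10 counts were higher and 74 were lower in the TQ library by the rule of size. The lower ones began with ciRNA105, with 61 counts in control and 0 in TQ, at least 8.48-fold lower against a floor of 3 counts, with an upper 99% limit of the ratio of 0.218. Next came circRNA5825, with 56 and 0 counts, at least 7.78-fold lower against that floor, with an upper limit of 0.238. The higher ones began with circRNA2993, with 0 counts in control and 22 in TQ, at least 17.6-fold higher against the floor (lower 99% limit 8.81), and circRNA13346, with 0 and 16 counts, at least 12.8-fold higher (6.11). Of the 74 lower identifiers, 43 had 0 counts in TQ, and of the 46 higher ones 9 had 0 in control. The balance of higher and lower depended on the scaling. Total counts gave 82 higher and 49 lower, and a factor from the abundant circRNAs gave 74 and 53. DESeq2 size factors gave 51 and 71, and TMM over every identifier with a count gave 24 and 169. The balance depended on the minimum of counts too: with none, 140 were higher and 74 lower. The median ratio of the 1130 identifiers was -0.32 on the log2 scale in the scaling used here, -0.07 with total counts and -0.82 with TMM over every identifier, so that the MiaPaCa-2 ratios stand against those medians.

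In PANC-1, 130 of 2289 identifiers were higher and 73 were lower in the TQ library. The higher ones began with circRNA5825, with 0 counts in control and 63 in TQ, at least 15.2-fold higher against the floor (lower 99% limit 8.25), and hsa_circ_0119881, with 0 and 55 counts, at least 13.3-fold higher (7.16). The lower ones began with circRNA32840, with 60 counts in control and 0 in TQ, at least 27.6-fold lower against the floor (upper 99% limit of the ratio 0.0668), and circRNA2993, with 42 and 0 counts, at least 19.3-fold lower (0.0973). Most of these calls rested on a zero: 109 of the 130 higher identifiers had 0 counts in control and 42 of the 73 lower ones had 0 in TQ. With the minimum of 10 counts, more identifiers were higher than lower under each of 5 scalings. The calls ran from 127 against 76 with DESeq2 size factors to 151 against 61 with TMM over every identifier. With no minimum of counts there were 130 higher and 150 lower. Under 10 counts the 99% interval could give only lower calls in PANC-1, whose control library was the shallower. The minimum kept out such lower calls, so the lean toward higher ones depended on it. Agreement over scalings does not bear on this, and the balance shows no direction of change.

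**Figure D2:**
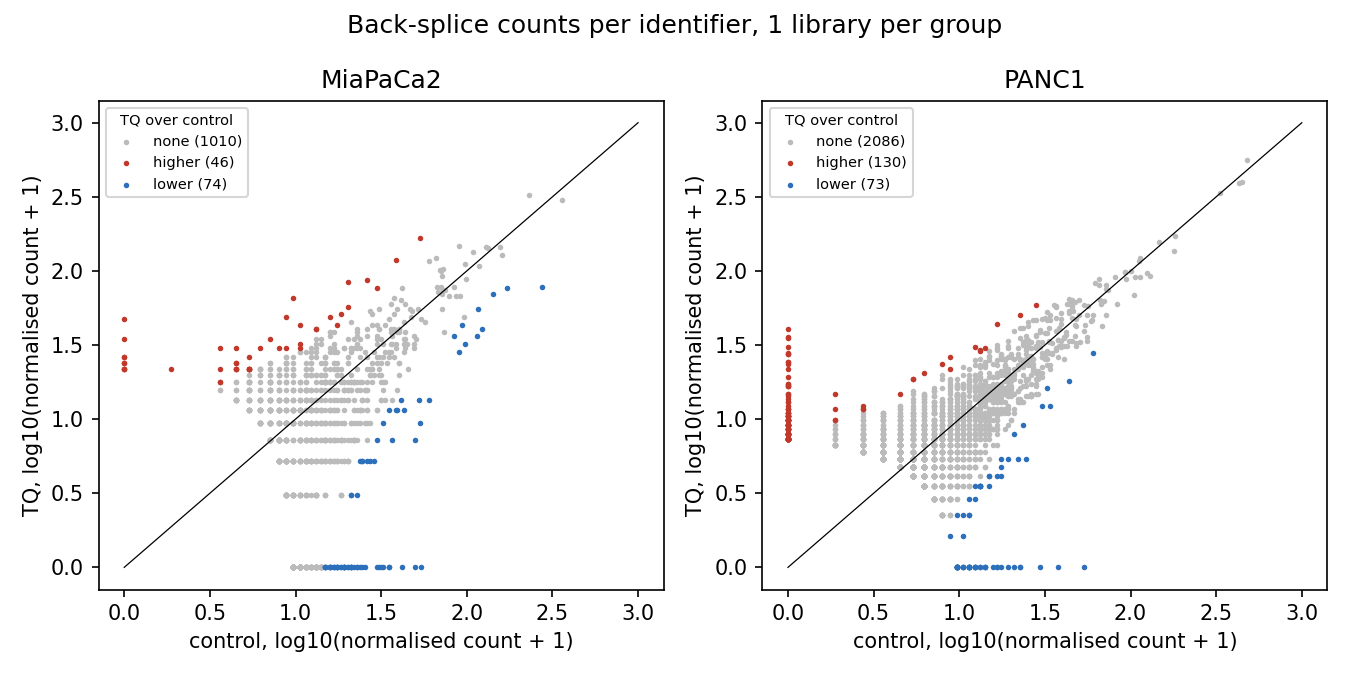
Normalised back-splice count in TQ against control, both as log10 of the count plus 1, for identifiers with at least 10 counts in MiaPaCa-2 (left, 1130) and PANC-1 (right, 2289). Red and blue points met the rule of size as higher (46 and 130) and lower (74 and 73) in TQ; points on an axis had 0 counts in one library.

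The 2 lines shared few calls. Among 777 identifiers with at least 10 counts in each line, 3 were higher in the TQ library of both, where independent lists would share 1.18, and 3 were lower in both, against 1.81. Fisher's exact test, two-sided, gave p = 0.109 and p = 0.416, or 0.437 and 0.546 after Benjamini-Hochberg adjustment over 4 overlaps. The shared higher identifiers with most counts were circRNA18221, with 22, 27, 0 and 37 counts in MiaPaCa-2 control and TQ and PANC-1 control and TQ, and hsa_circ_0050119, with 7, 16, 0 and 11. The shared lower ones were circRNA2997, with 44, 5, 33 and 0 counts, and hsa_circ_0008344, with 23, 0, 19 and 0. Another 4 identifiers were lower in MiaPaCa-2 TQ and higher in PANC-1 TQ, and 1 went the other way, where independent lists would give 2.80 and 0.764 (Fisher's exact test, p = 0.516 and 0.546, both 0.546 after adjustment). The first of these, hsa_circ_0001278, had a ratio of 0.160 (99% interval 0.0259 to 0.541) in MiaPaCa-2 and 2.29 (1.27 to 4.38) in PANC-1. The log2 ratios of the 2 lines had a Pearson r of -0.07 (95% interval -0.14 to 0.0032, permutation p = 0.0619) and a Spearman rho of -0.09 (permutation p = 0.0104) across identifiers, which are not independent replicates. The r was -0.37 among the 75 identifiers with at least 50 counts in each line and -0.18 among the 653 with no 0 in any library.

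With the lines as the only replication of the treatment, edgeR's quasi-likelihood test with a term for cell line called 0 of 827 tested identifiers higher and 0 lower in TQ at a false discovery rate of 0.05. At an unadjusted p under 0.05 it gave 5, and DESeq2 called 0 with 8 unadjusted. Both numbers were under the share of 0.05 of those tested that chance alone would give. The lowest adjusted p of edgeR was 0.998. On simulated counts with the spread edgeR estimated, the test recovered 0% of identifiers changed 2-fold, 0% of those changed 4-fold and 52% of those changed 8-fold.

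Between the lines, circRNA12135 was higher in PANC-1, with 495 and 625 counts in control and TQ against 9 and 4 in MiaPaCa-2. Its log2 fold change was 5.67 (SE 0.24, adjusted p = 0.0368 by edgeR's quasi-likelihood test), with both PANC-1 libraries above both MiaPaCa-2 libraries. It was the 1 identifier called higher in PANC-1, and 0 of 827 were lower, with 146 at an unadjusted p under 0.05. With treatment in the model, the p-values measure how far the difference between TQ and control varied between the lines. The count was not stable: DESeq2 called 41 higher and 26 lower, and edgeR without the treatment term called 92 and 66. Without MiaPaCa-2 control, a fit that also had no treatment term and tested 1260 identifiers called 340 higher and 92 lower.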

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

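The tests of counting error, of losses in single libraries, of neighbouring numbers and of the scaling were chosen only after the result they bear on, or part of it, had been seen; for the tests that thin libraries, what they should show was written before their results were seen, though thinning the calls was itself added after the data had been examined. None of the differences between the lines was tested against a spread between replicates, since each line had 1 library per treatment, and dose differed with the line.

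The total back-splice count in TQ was 0.351 of control in MiaPaCa-2 and 1.40 of control in PANC-1, in opposite directions. Depth alone predicts that thinning the deeper library gives as many identifiers as the shallower one. The MiaPaCa-2 TQ library, with 5089, had 0.765 times the identifiers of its thinned control, which had 6589 to 6761 over 100 thinnings. PANC-1 control, with 12081, had 0.923 times those of the thinned TQ library, which had 13020 to 13176. Both lay outside the range, which was written beforehand as the outcome if depth alone was not the cause. At a minimum of 2 reads the ratio of TQ to control, all libraries thinned to the smallest total, was 1.03 in MiaPaCa-2 and 0.952 in PANC-1, the opposite order. The range of thinnings holds sampling noise within 1 library, and without replicates it cannot show how far 2 libraries of one kind would differ. Meeting that criterion therefore does not tell depth apart from the treatment here. Digestion of linear RNA, copies made in PCR and an effect of TQ on circRNA amount stay open, and none was tested.

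In MiaPaCa-2 most calls were lower in TQ and in PANC-1 most were higher. With the factor from the abundant circRNAs, 41.7% of MiaPaCa-2 calls were lower (95% interval 33.0 to 50.8), which includes an even split, against 61.7% with the scaling of the report, 87.6% with TMM over every identifier and 37.4% (29.1 to 46.3) with total counts, which leans the other way. DESeq2 size factors gave 58.2% (48.9 to 67.1), which also includes an even split. The direction of the MiaPaCa-2 lean thus depended on the factor chosen, and which factor is right was not tested. The intervals take the called identifiers as independent, though all share the same factor, so they leave out the uncertainty of the scaling. With no minimum of counts both leans turned, to 140 higher and 74 lower in MiaPaCa-2 and 130 higher and 150 lower in PANC-1. Under 10 counts only higher calls were possible in MiaPaCa-2 and only lower ones in PANC-1. Both leans thus depended on the minimum, and neither shows a direction of change. When PANC-1 was thinned to the MiaPaCa-2 totals, 73 of 100 thinnings gave more higher than lower calls, where 95 were asked for in advance, so the difference in depth between the lines cannot be told apart from a difference in response: too few calls were left, on average 15.5 higher and 12.4 lower.

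Many identifiers had at least 10 expected counts in one library of a line and 0 observed. There were 112 of 773 that could show this in MiaPaCa-2 and 122 of 1351 in PANC-1, 234 in all, while 1000 simulations of counting error gave at most 7 and 5, which argues against counting error. In MiaPaCa-2, 97 were at 0 in control and 15 in TQ, and in PANC-1 49 and 73. The same measure between the 2 control libraries gave 237. These splits show no direction of change, since fewer counts in the shallower library sufficed for 10 expected in the deeper one. Zeros among the called identifiers leaned the other way, with 9 in control and 43 in TQ in MiaPaCa-2 and 109 and 42 in PANC-1. These show no direction of change either, since the deeper library reaches the minimum of 10 counts more readily. The simulations took counts as independent, so copies made in PCR stay open. A circle may also have been booked under another number in the other library. Of 127 numbered identifiers, 7.09% had a reverse switch within 5 numbers (upper 95% limit 13.03%). The circBase identifiers, 45 in MiaPaCa-2 and 62 in PANC-1, were not searched. Without coordinates, close numbers need not be neighbouring circles, so the search cannot decide on such bookings. Single identifiers stay open to them. In MiaPaCa-2 control and TQ, circRNA5825 had 56 and 0 counts and the next number, circRNA5826, had 0 and 12. Both were higher in PANC-1 TQ, with 0 and 63 and 0 and 15. In MiaPaCa-2 circRNA2993, with 0 and 22, and circRNA2997, with 44 and 5, also went opposite ways, and in PANC-1 both had 0 in TQ. Of the 7 identifiers that switched in both lines, 3 (42.9%, 95% interval 9.90 to 81.6) switched in opposite directions, as losses in single libraries unrelated to treatment may give, but 7 are few. This set and the calls overlap only in part. In the set, 88 of the 97 at 0 in MiaPaCa-2 control and 31 of the 73 at 0 in PANC-1 TQ had under 10 counts over the line. They were not considered for a call. Of the 43 lower calls at 0 in MiaPaCa-2 TQ, 15 were in the set, and of the 109 higher calls at 0 in PANC-1 control, 49. Beyond counting error the explanation of the set stays open, and an effect of TQ that differs by line was not tested.

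As TQ minus control, the share of circBase counts differed by -1.96 percentage points in MiaPaCa-2 and 0.903 in PANC-1, and the ciRNA share differed by 1.76 and -1.17 points, opposite in the lines. There were 4 identifiers lower in MiaPaCa-2 and higher in PANC-1, and 1 with the reverse, against 2.80 and 0.764 for independent lists (Fisher's exact test, p = 0.516 and 0.546), so neither number stood beyond chance. The ratio of the MiaPaCa-2 ratio to the PANC-1 ratio was 0.282 for the HIPK3 circle and 0.426 (99% interval 0.188 to 0.964) for the LDLRAD3 circle, from counting error alone. Both values hold for the scaling of the report only. With total counts the LDLRAD3 ratios were 0.915 in MiaPaCa-2 and 1.79 in PANC-1, which are closer together. DESeq2 size factors gave 0.792 and 1.75, also closer together. No interval was computed under these scalings, and the LDLRAD3 interval was 1 of 6 with no allowance for that. With TMM over every identifier they were 0.547 and 2.08, which are farther apart.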

How the results depend on the processing

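The filtered TMM of the report was itself chosen after the calls with TMM over every identifier had been seen. That version as an alternative, leaving out identifiers at 0, counting calls after thinning and the fixed circRNAs under other scalings were also chosen after seeing the data; the other alternatives were planned, and the causes of the shifts were not tested except where fewer identifiers or a looser rule explain them. In MiaPaCa-2 the 46 higher and 74 lower calls became 82 and 49 with total counts, 24 and 169 with TMM over every identifier, 5 and 18 at a minimum of 50 counts, 96 and 189 with a 95% interval and 28.2 and 37.2 with control thinned to the TQ total. With no minimum there were 140 higher and 74 lower, and without identifiers at 0 in either library 37 and 31. DESeq2 size factors changed the calls little, to 51 and 71. In PANC-1 the 130 higher and 73 lower became 10 and 6 at a minimum of 50, 21 and 31 without identifiers at 0, and 15.5 and 12.4 when thinned to the MiaPaCa-2 totals. Leaving out identifiers at 0 removes the strongest differences by construction, so it shows nothing on the balance. PANC-1 had 130 higher and 150 lower with no minimum, and 171 and 125 with a 95% interval. Under 10 counts only higher calls were possible in MiaPaCa-2 and only lower ones in PANC-1. The minimum kept these out, so the balance depended on it in both lines and shows no direction of change. Shared calls, 3 in each direction, became 0 and 0 at a minimum of 50. The correlation between lines became -0.37 at that minimum and -0.18 without identifiers at 0.

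For TQ over both lines every alternative with 4 libraries called 0; leaving out 1 library gave 0 to 1 higher and 0 to 0 lower, the 1 without PANC-1 TQ. Between the lines, the 1 higher and 0 lower identifiers became 41 and 26 with DESeq2, 47 and 44 with total counts, 10 and 5 with no filter and 92 and 66 with no treatment term. Fits without 1 library also dropped the other factor from the model and tested 1154 to 1346 identifiers instead of 827, so they are not the effect of that library alone. With the lone library of a line assumed to vary like the others, they gave 1 to 340 higher and 0 to 92 lower; 340 and 92 came without MiaPaCa-2 control, 139 and 73 without MiaPaCa-2 TQ and 47 and 31 without PANC-1 TQ. The ratio of identifiers detected, 0.765 in MiaPaCa-2 and 1.03 in PANC-1, was 0.458 and 1.24 without thinning and 1.03 and 0.952 at 2 reads. Of 36 recomputed ratios of fixed circRNAs, 34 kept their side of the rule; with TMM over every identifier ZKSCAN1 in MiaPaCa-2 reached 0.369 and LDLRAD3 in PANC-1 reached 2.08, and both met it. The HIPK3 ratio in MiaPaCa-2 was 0.201 to 0.336. Sums per host gene and list medians were not run. No cell line term (no replicate block) gave 0 calls for TQ.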
